A study of Mus musculus with 12 samples.

How the data were processed

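The mammary glands of 12 mice were profiled on Affymetrix arrays of 45101 probe sets, 1 biotin-labelled sample per array. Per the labels' protocols, virgin mice were ovariectomized, treated for 7 days with placebo or with estradiol-releasing pellets (0.72 mg, 60-day release), and RNA was extracted with Trizol. Per the series description the mice were separate animals, 6 wildtype and 6 knockout for Ccnd1, with 3 of each on placebo and 3 on estradiol. The labels do not say which gland was taken or whether its lymph node was removed.

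The deposited values are log2 intensities that the authors normalised over the 12 arrays. Per the submitters' processing notes RMA (background correction, quantile normalisation and a summary per probe set) and limma 2.9.16 were used, with no version of RMA or of the chip definition. That the scale is log2 was checked on the values, whose array medians lie between 5.7 and 5.8 and none of which is below 0. Arrays have no sequencing depth, and their number limits the precision.

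The platform table links 34945 probe sets to 1 gene, 932 to several and 9160 to none, beside 64 control probe sets. Each of the 18193 genes was represented by its probe set with the highest mean over all 12 arrays, chosen without regard to group, and 9010 genes had more than 1. No filter on dim genes was applied. A RefSeq gene table matched 18029 genes and served only to find genes that neighbour each other. No positions are given, since the deposited files name no genome build.

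All comparisons come from 1 limma fit (limma 3.58.1 in R 4.3.3) of 4 group means with eBayes moderation, which left 8 residual and 2.15 prior degrees of freedom. The 5 main comparisons are the estradiol effect in each genotype, the genotype effect under each treatment and their interaction. Besides these, the average estradiol and average genotype effects were computed, 7 in all. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. Differences are estradiol minus placebo or knockout minus wildtype, and the interaction is the knockout response minus the wildtype response. Ccnd1 was tested on its own by an exact two-sided permutation of the 6 knockout and 6 wildtype arrays.

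In total 35 gene lists, covering hormone response, the cell cycle, cell types of the gland and its surroundings, metabolism, signalling and immune response, were fixed with 716 members, of which 663 were measured. Each was tested with limma's camera at a preset correlation between genes of 0.01, with camera at a correlation estimated per list, and with fry, adjusted over the lists. The preset correlation lies below that of genes expressed in a cell type whose share varies, so the result with the estimated correlation stands beside each call. Scores per array are list means of log2 values centred over the 12 arrays, and the lymphocyte score is the mean of the T and B cell scores.

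The named genes follow a rule. It takes Ccnd1, the other D-type cyclins, both estrogen receptor genes, Pgr, Greb1 and Areg as a fixed set; Areg is linked to no probe set of its own here. It adds the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, and, where fewer than 10 genes are called, the 10 with the smallest p. From each list with a call it takes up to 4 called members, or the 2 with the smallest p where no member is called. Genes with only a clone name are counted but need not be named. The groups, the comparisons, this rule, the gene lists and most alternatives were set before the data were examined.

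On data simulated with 200 changed genes among 18193, the test recovered 58.5%, 89.0% and 93.0% of changes of 1, 2 and 3 log2 units in the wildtype estradiol comparison and 32.5%, 79.0% and 89.5% in the interaction. The simulated genes varied independently of each other, unlike genes of a cell type whose share varies. These shares therefore need not hold for the measured arrays. The alternatives tried were the mean of all probe sets or each probe set on its own, leaving out the dimmest 40% of genes, quantile or median scaling, eBayes with a trend and robust priors, array weights, the replicate number as a block, other thresholds, fits of the 6 arrays concerned, and leaving out each array. Covariates for lymphocyte, muscle and luminal content and for the 3' minus 5' difference of the Gapdh control probe sets, and the omission of 2 arrays poor in lymphocyte genes were added after the data had been seen. No array was left out of the results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.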

Results

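Total RNA from the mammary glands of 12 ovariectomized virgin C57BL/6 mice was measured on 12 single-colour Affymetrix arrays, in 4 groups of 3. The mice were wildtype or knockout for Ccnd1, which encodes cyclin D1, a partner of the kinases that drive cells from G1 into S phase. Each genotype received placebo or estradiol pellets (0.72 mg, 60-day release) for 7 days. The study's title asks whether cyclin D1 determines the gland's response to estrogen, which the interaction of genotype and treatment addresses most directly. Values are log2 intensities of 18193 genes, and the array medians lay between 5.7 and 5.8. Pairs of arrays correlated at 0.937 to 0.993 across genes, no 2 arrays were identical, and 8 of the 12 arrays had their closest partner in their own group. The number of arrays limits the precision of every value below.

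Ccnd1 was lower in the knockout arrays. Its mean log2 level was 8.81 ± 0.34 (SD, n = 3) in wildtype placebo, 10.02 ± 0.74 in wildtype estradiol, 7.56 ± 0.11 in knockout placebo and 7.41 ± 0.16 in knockout estradiol. The 6 knockout arrays ranged from 7.24 to 7.68 and the 6 wildtype arrays from 8.50 to 10.8. The difference, knockout minus wildtype, was -1.93, with an exact two-sided permutation p of 0.00216 over 924 arrangements, the smallest these can give. The gene's other probe sets differed by -0.90 and -1.0. Where the probes lie relative to the deleted part of the gene is not known here, so the remaining signal cannot be read as transcript. In the limma fit Ccnd1 was 2.62 lower in knockout than in wildtype under estradiol (log2 difference -2.62, adjusted p = 0.0094), and its estradiol difference in wildtype was 1.22 ± 0.31 (SE, adjusted p = 0.089), which did not pass. The call under estradiol was lost without knockout estradiol array 3, where the difference was -2.53.

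Estradiol in wildtype glands asks what the hormone did to the intact tissue. The largest measured rise was that of Mmd2, from 6.00 ± 0.04 to 12.44 ± 0.26 (SD, n = 3), a log2 change of 6.44 ± 0.14 (SE, adjusted p = 1.01e-08). Greb1, a gene named for its regulation by estrogen in breast cancer cells, rose by 5.83 ± 0.27 (adjusted p = 7.46e-06) and Pgr, the progesterone receptor, by 3.06 ± 0.34 (adjusted p = 0.0025). Ido1, a tryptophan-degrading enzyme, rose by 5.77 ± 0.64 (adjusted p = 0.0025), the chemokine Cxcl15 by 4.97 ± 0.48 (adjusted p = 0.0013) and the oxytocin receptor Oxtr by 4.46 ± 0.65 (adjusted p = 0.0084). Gas6, a ligand of the Axl family of receptor kinases, rose by 3.90 ± 0.22 (adjusted p = 3.38e-05). Akr1cl, the protease Tmprss11a, the collagen-modifying enzyme Plod2, the neurotrophin receptor Ngfr, the matrix protein Spon1 and the monocarboxylate transporter Slc5a8 rose by 3.63 to 3.92. In all 3 wildtype placebo arrays, Greb1, Tmprss11a and Cel, a lipase named below, lay under the lower quartile of the same array (highest values 3.98, 2.73 and 4.17), so their rises are at least the values given.

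Falls in wildtype were fewer and smaller, though their number rested on 1 array, as given below. H2-Q10, a class I histocompatibility gene, fell by 1.67, the interferon-induced chemokine Cxcl9 fell by 1.64, the T cell transcription factor Tbx21 fell by 1.14 and Cd274, the ligand of the checkpoint receptor PD-1, fell by 1.04. Pcdh17 fell by 1.07, the pericyte gene Rgs5 fell by 0.89, Gba2 fell by 0.71, Gpat2 fell by at least 0.68 (its 3 estradiol arrays lay under the lower quartile) and Cep95 fell by 0.60. Another probe set of Gba2 and of Cep95 had the opposite sign (0.016 and 0.18). The lymphocyte score, which averages T and B cell marker genes, was lower in the 3 wildtype estradiol arrays (-1.85, 0.68 and -2.03) than in 2 of the 3 placebo arrays (2.21, 1.63 and -1.90). The estrogen receptor genes and the other D-type cyclins did not pass the test, with differences of -0.44 for Esr1, -0.05 for Esr2, -0.06 for Ccnd2 and 0.01 for Ccnd3. The sign of the Ccnd3 value turned under quantile scaling.

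In all, limma called 342 genes in wildtype, of which 333 rose and 9 fell. In each of the 342 the 3 estradiol arrays lay all above or all below the 3 placebo arrays, as did 17.0% of all genes, where chance gives 10%. The count depended on single arrays: it was 107 without wildtype placebo array 1, 100 without array 2, 1146 without array 3 (915 higher and 231 lower), and 153 without wildtype estradiol array 3. With the luminal score as a covariate, added after the data were seen, it was 12, and 5 of the 58 named calls stayed. The median size of the 342 differences went from 1.37 (SE 0.225) to 1.33 (SE 0.325), with all 342 signs kept. That score was itself higher under estradiol (1.55 ± 0.80 against 0.04 ± 0.22, SD). Of the 58 named calls in wildtype, 21 stayed past the threshold whichever array was left out, among them Mmd2, Greb1, Gas6, Ido1, Cxcl15, Oxtr, Pgr and Slc5a8.

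Among gene groups, camera with its preset correlation called lists of mammary epithelium higher under estradiol in wildtype. Of 16 measured basal and myoepithelial genes, 6 rose and none fell (12 rose when adjusted over the list alone), among them Oxtr, the contractile genes Cnn1 (1.97) and Acta2 (1.59), and Pdpn (1.41). Of 21 luminal genes, 1 rose, Prom1 by 2.07 (14 when adjusted over the list alone), and the list's median difference was 1.64. Of 30 estrogen target genes 4 rose (7 when adjusted over the list alone), namely Greb1, Pgr, Lcn2 (2.87), an iron-binding secreted protein, and Tfap2c (2.80), a transcription factor of the mammary epithelium. The camera test gave adjusted p = 3.1e-11 for the basal, 4.0e-10 for the luminal and 0.029 for the estrogen target list, and each of these had adjusted p = 0.36 with an estimated correlation. By fry, which asks whether a list's genes move one way on balance, the adjusted p was 0.0044 for the basal, 0.032 for the luminal and 0.0044 for the estrogen target list.

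Camera also called lists of stromal, myeloid and interferon response genes in wildtype. Of 28 fibroblast and matrix genes 4 rose (20 when adjusted over the list alone), among them the protease inhibitors Timp1 (2.67) and Timp2 (1.47), the matrix protease Mmp14 (1.84) and the receptor Pdgfra (1.72), and all 28 differences were above 0. Of 23 macrophage and myeloid genes 3 rose (14 when adjusted over the list alone): the immunoglobulin receptors Fcgr1 (3.00) and Fcgr3 (1.86), and Cd14 (1.81), a co-receptor for bacterial lipopolysaccharide, while 5 of the 23 differences were below 0. Wildtype estradiol array 1 stood apart in this list, whose score was 1.32, 0.10 and 0.36 in the estradiol arrays and -0.43, -0.24 and -0.57 in the placebo arrays, with Fcgr1 at 10.02, 7.86 and 8.27 under estradiol. Without that array the mean difference of the list was 0.64 instead of 1.01. Of 22 interferon response genes 5 rose and 1 fell (12 and 1 when adjusted over the list alone), with Oasl2 at 3.23, Oas1a at 2.46, Irf7 at 2.03 and, in the other direction, Cxcl9. Wildtype estradiol array 1 stood apart here too, with interferon scores of 0.95, 0.28 and 0.29 under estradiol and -0.54, -0.27 and -0.33 on placebo. The adjusted p by camera was 2.9e-13 for the fibroblast, 1.4e-06 for the macrophage and 5.0e-06 for the interferon list, against adjusted p = 0.36 with an estimated correlation for each.

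Some genes of signalling lists passed as well. Of 17 immediate early genes 4 rose (4 when adjusted over the list alone), namely Egr2 (3.06), Ccn1 (2.15), Ier3 (1.53) and Jun (0.87), with adjusted p = 0.0014 by camera and adjusted p = 0.36 with an estimated correlation. Of 32 Wnt and Notch genes 3 rose (8 when adjusted over the list alone): the Wnt agonist Rspo1 (2.34), the Wnt inhibitor Sfrp1 (1.85) and Dkk3 (1.09), at adjusted p = 4.6e-04 by camera and adjusted p = 0.46 with an estimated correlation. Of 16 genes of the EGF family 2 rose (4 when adjusted over the list alone), the receptors Egfr (1.78) and Erbb3 (1.60), at adjusted p = 0.035 by camera and adjusted p = 0.36 with an estimated correlation. Outside the lists that camera called, Stat5a (0.98) and its target Socs2 (1.28), Sox10 (1.68) and Ncam1 (1.66) of the Schwann cell list, Igfbp2 (0.83) and the cell cycle inhibitor Cdkn2b (0.55) also rose. So did Sdc1 (2.63) of the plasma cell list, the lipase Cel (1.89), the clock gene Nfil3 (1.85), Hspa1b (1.80) and Trib3 (1.44). The plasma cell score did not rise with Sdc1, averaging 0.02 ± 0.95 in wildtype placebo and -0.43 ± 0.90 in wildtype estradiol (SD). Sox10 was highest in wildtype estradiol array 2 (9.52), whose Schwann cell score was the lowest of its group (-0.02). Some genes of this paragraph had another probe set of the opposite sign, at -0.054 for Egfr, -0.17 for Erbb3 and -0.044 for Ncam1.

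Lists that were lower under estradiol in wildtype had no called member. The median difference was -2.02 for 16 B cell genes, -1.88 for 17 T cell genes, -0.93 for 13 brown adipocyte genes, -0.29 for 18 cholesterol synthesis genes and -0.23 for 34 genes of oxidative phosphorylation. By camera the adjusted p was 0.0014, 5.5e-04, 0.0041, 0.029 and 1.4e-05 in that order, and with an estimated correlation the adjusted p was 0.74, 0.68, 0.68, 0.78 and 0.68. The mean difference rested on single arrays in each: it went from -1.82 to -1.01 for B cell and from -1.61 to -0.86 for T cell genes without wildtype placebo array 1, and to -3.20 and -2.77 without array 3. It went from -1.06 to -0.59 for brown adipocyte genes without wildtype estradiol array 1, and without wildtype placebo array 3 from -0.26 to -0.02 for cholesterol synthesis and from -0.23 to -0.15 for oxidative phosphorylation. Mast cell genes had a median of 0.52, with adjusted p = 0.0053 by camera and adjusted p = 0.60 with an estimated correlation. Camera with its preset correlation called 15 of the 35 lists in wildtype, fry 9, and camera with estimated correlations 0. Limma gave an unadjusted p under 0.05 for 2450 genes, where chance gives 910.

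Estradiol in knockout glands asks how much of the response needs no cyclin D1. Mmd2 rose there by 6.15 (adjusted p = 1.61e-08), from 6.70 ± 0.21 to 12.84 ± 0.08 (SD, n = 3), Greb1 by 4.41 and Gas6 by 3.65 (both adjusted p = 7.76e-05). Nexmif, under the lower quartile in the 3 placebo arrays, rose by at least 3.12 (adjusted p = 5.09e-04), Ngfr by 2.48, Spon1 by 2.32, the secreted glycoprotein Lrg1 by 2.28, the fibrinogen-like protein Fgl1 by 2.22, Plppr3 by 1.68, Gadd45gip1 by 1.62, Fbxw17 by 1.39 and Socs2 by 1.10. Gpc6, a cell surface proteoglycan, fell by 1.35 (SE 0.20, adjusted p = 0.049). Other probe sets of Gadd45gip1 and Socs2 reached -0.19 and -0.095. Pgr did not pass, with a difference of 1.61 ± 0.34 (SE, adjusted p = 0.199), nor did Oxtr, which averaged 7.96 ± 1.13 on placebo and 11.81 ± 0.18 on estradiol (SD). Pgr lay under the lower quartile in knockout placebo arrays 1 and 2, and Greb1 in arrays 1 and 3. The differences of Pgr and Greb1 are therefore not exact sizes.

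The knockout count was 18 genes, 17 of them higher and 1 lower, with 1513 at an unadjusted p under 0.05, where chance gives 910. In all 18 the groups did not overlap, as in 13.5% of all genes, where chance gives 10%. It was 11 without wildtype placebo array 2, 10 without wildtype estradiol array 1, 10 without knockout placebo array 1 or 2, and 11 without knockout estradiol array 1. Of 14 named calls, 8 held whichever array was left out: Mmd2, Greb1, Gas6, Nexmif, Lrg1, Fgl1, Fbxw17 and Plppr3. Camera called 4 lists, none with a called member. Of 39 genes of the S, G2 and M phases all 39 differences were below 0 (median -0.60, adjusted p = 4.9e-06), and for 22 interferon response genes the median was 0.55 (adjusted p = 2.6e-06), of which 9 rose and 1 fell when adjusted over the list alone, with Irf7 at 1.88 and Rtp4 at 1.37. Knockout estradiol array 1 stood apart in the interferon score, which was 0.69, 0.02 and 0.14 under estradiol and -0.45, -0.46 and -0.33 on placebo. The cell cycle score was 0.87, -0.89 and 1.09 in the knockout placebo arrays, whose lymphocyte scores were 1.73, -1.89 and 1.83, and -0.85, 0.37 and -0.27 in the knockout estradiol arrays, whose lymphocyte scores were -2.04, 1.39 and 0.25. The mean of the cell cycle list was -0.60, but -1.23 without knockout placebo array 2, -0.23 without array 3 and -0.30 without knockout estradiol array 1. The medians were 0.23 for lipogenesis (adjusted p = 0.046) and 0.17 for oxidative phosphorylation (adjusted p = 0.0089), whose means went from 0.25 to 0.12 without knockout estradiol array 3 and from 0.20 to 0.036 without array 1. Each of the 4 lists had adjusted p = 0.88 with an estimated correlation, and fry called 0. The number of lists was 10 without knockout placebo array 2 or knockout estradiol array 2, and 8 without knockout estradiol array 1.

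**Figure D1:**
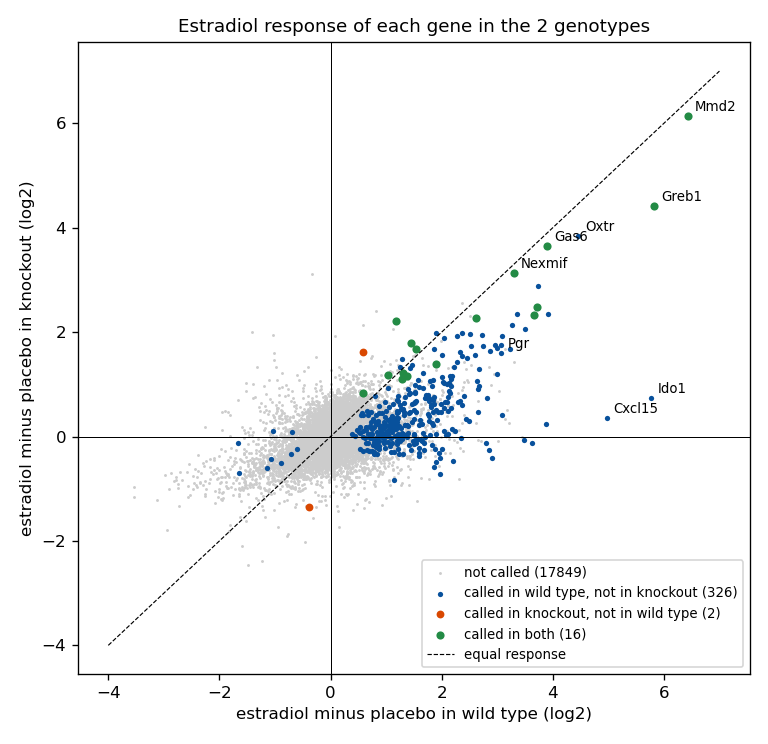
Log2 difference between estradiol and placebo for each of 18193 genes, in wildtype on the horizontal and in knockout on the vertical axis, coloured by the comparison in which limma called the gene. The 16 genes called in both genotypes lie on the same side of 0 on both axes, and Mmd2 is at 6.44 and 6.15.

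Across genotypes, 16 genes were called in both, all in the same direction, where 0.338 would be called in both if the calls were independent. The calls are not independent, since both tests use the same estimate of each gene's spread, so 0.338 is not a fair measure of chance. Among the 16 are Mmd2, Greb1, Gas6, Nexmif, Ngfr, Spon1, Lrg1, Fgl1, Fbxw17, Plppr3 and Socs2. The 16 became 10 without wildtype placebo array 1, knockout placebo array 1 or knockout estradiol array 1 or 2, and 9 without wildtype placebo array 2, wildtype estradiol array 1 or knockout placebo array 2. Of the 342 genes called in wildtype, 260 (76.0%) had the same sign in knockout and 117 had an unadjusted p under 0.05 there. Their choice in wildtype favours a larger value in wildtype, so the average effect over both genotypes was also used, a choice that favours neither genotype but does favour genes with the same sign in both. It called 287 genes (261 higher and 26 lower), of which 229 had a smaller difference in knockout, with a slope of knockout on wildtype of 0.534. Error in the wildtype values lowers this slope even where the responses are equal, so it does not measure the size of the knockout response. The count of 287 was 1400 without wildtype placebo array 3, 127 to 136 without any 1 of wildtype placebo arrays 1 and 2 and knockout placebo arrays 1 and 3, 147 without wildtype estradiol array 3, and 168 and 173 without knockout estradiol arrays 1 and 2. Across all genes, which are not independent replicates, the 2 responses correlated at Pearson 0.472 and Spearman 0.365, and at Pearson 0.307 without knockout estradiol array 1.

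The interaction tests whether the estradiol response differed between genotypes. Padi4, an enzyme that converts arginine to citrulline in proteins, went from 4.25 ± 0.11 to 6.49 ± 0.35 in wildtype and from 4.61 ± 0.08 to 4.72 ± 0.12 in knockout (SD, n = 3), an interaction of -2.14 ± 0.23 (SE). Anln, a scaffold protein of cytokinesis, went from 6.32 ± 0.09 to 7.45 ± 0.19 in wildtype and from 6.77 ± 0.23 to 5.95 ± 0.22 in knockout, an interaction of -1.96 ± 0.22. These 2 genes passed, each at adjusted p = 0.0378. Cxcl15 had -4.61 ± 0.67 (adjusted p = 0.126), Acta2 -1.90 (adjusted p = 0.139), Pgr -1.45 ± 0.48 (adjusted p = 0.58) and Greb1 -1.41 ± 0.38 (adjusted p = 0.40), none of which passed. Among the genes with the smallest p that did not pass were Prom2 at -1.44 (adjusted p = 0.089), the smooth muscle actin Actg2 at -2.40 (adjusted p = 0.098), Cthrc1 at -3.11, Ano4 at -1.60, Serpinb11 at -2.36 and the angiotensin receptor Agtr2 at -1.16. Agtr2 lay under the lower quartile of each array outside wildtype estradiol, Ano4 in both placebo groups and Serpinb11 in wildtype placebo. Greb1 did so in wildtype placebo and in knockout placebo arrays 1 and 3, and Pgr in knockout placebo arrays 1 and 2. The interactions of all these genes are therefore not exact sizes.

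At the level of single genes, then, 2 interactions were called against 1170 at an unadjusted p under 0.05, where chance gives 910. The count was 0 without wildtype placebo array 1 or 2, any of the knockout placebo arrays, or knockout estradiol array 2 or 3. It was 1 without wildtype estradiol array 2 or 3, 5 without knockout estradiol array 1, 17 without wildtype placebo array 3 and 18 without wildtype estradiol array 1. Neither Padi4 nor Anln kept its call throughout, and 0 genes were called with the Gapdh 3' minus 5' difference as a covariate, added after the data were seen. With that covariate the median size of the 2 interactions was 1.99 (SE 0.225), against 2.05 (SE 0.223) without it.

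By camera 19 lists differed in their response. The median interaction was -1.79 for the 21 luminal genes (adjusted p = 5.9e-12), -0.97 for the 16 basal genes (adjusted p = 5.8e-12), -1.28 for the 28 fibroblast genes (adjusted p = 6.7e-16) and -0.76 for the 39 genes of S, G2 and M phase (adjusted p = 3.5e-05). The adjusted p with an estimated correlation was 0.34, 0.29, 0.34 and 0.69 in that order. Adjusted over the list alone, 9 basal, 2 fibroblast, 1 luminal and 0 cell cycle genes passed, all with a lower response in knockout, while over all genes 0 members of these lists passed in limma. Estimated correlations and fry each left 0 of the 35 lists called. The cell cycle score ordered the arrays as the lymphocyte score did in wildtype placebo (0.48, 0.19 and -1.18 against 2.21, 1.63 and -1.90) and both knockout groups, but not in wildtype estradiol (-0.18, 0.45 and -0.08 against -1.85, 0.68 and -2.03). With the lymphocyte score as a covariate, an alternative added after the data were seen, the median interaction of the cell cycle list was -1.24 (adjusted p = 0.22 with an estimated correlation), and 19 of its 39 genes rose in wildtype, where 0 did without it. The mean interaction of that list was -0.84, but -0.34 without wildtype placebo array 3 and -1.46 without knockout placebo array 2. The muscle score lay between -2.84 and 1.92 in knockout placebo.

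**Figure D2:**
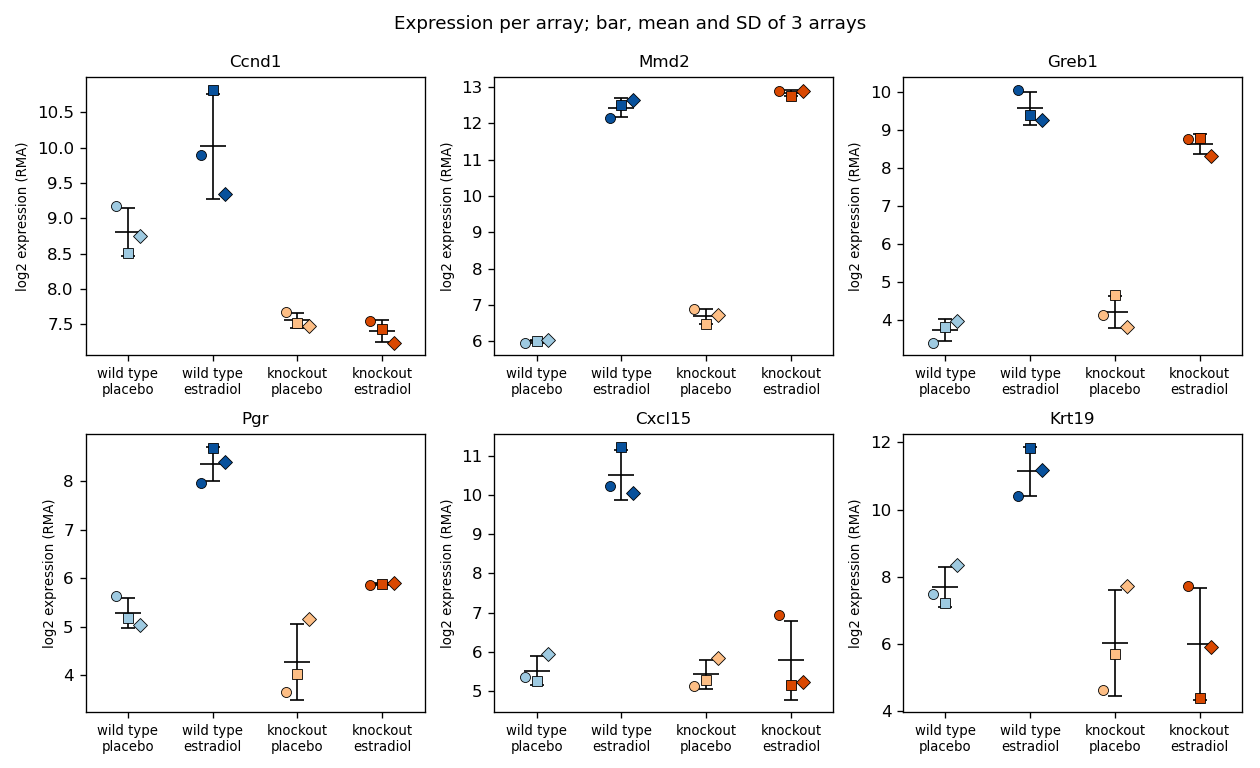
Log2 level of Ccnd1, Mmd2, Greb1, Pgr, Cxcl15 and Krt19 in each array, by group; circle, square and diamond are replicates 1, 2 and 3, and the bar and line give the mean and SD of 3. Mmd2 averages 12.44 and 12.84 in the estradiol groups, whereas Cxcl15 averages 10.49 in wildtype and 5.78 in knockout estradiol.

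Knockout against wildtype under placebo asks what the loss of cyclin D1 did without the hormone. No gene passed. Fgg, a fibrinogen chain, differed by -3.23 (knockout minus wildtype), Clca3a2 by -3.07 and Svs4 by -2.88. Pfkfb4, a regulator of glycolysis, differed by -0.59, Mmd2 by 0.69, Rhd by 0.49, the prokineticin receptor Prokr1 by 0.44 and Rims2 by 0.41, all among the genes with the smallest p. All knockout placebo values of Svs4 (3.26, 2.69 and 3.45) and its value in wildtype placebo array 3 (4.06) lay under the lower quartile of their array. Its difference is therefore not an exact size. Ccnd1 differed by -1.25, Pgr by -1.01 and the luminal transcription factors Elf5 by -2.22 and Foxa1 by -2.66. Knockout placebo array 3 was nearer to wildtype than arrays 1 and 2 in the last 3 genes: Foxa1 was 4.31, 4.46 and 8.32 in knockout and 8.53, 7.93 and 8.62 in wildtype, Elf5 was 6.24 in that array and at least 6.34 in wildtype, and Pgr was 3.64, 4.03 and 5.15 against 5.64, 5.18 and 5.04. Pgr and Elf5 lay under the lower quartile in knockout placebo arrays 1 and 2, so their differences are not exact sizes either. Limma called 0 genes, with a smallest adjusted p of 1.0 and with 370 at an unadjusted p under 0.05, where chance gives 910. Groups did not overlap for 6.71% of genes, where chance gives 10%. The count was 2 without wildtype placebo array 3. On simulated data with 200 genes changed by 1, 2 or 3 log2 units, the same test recovered 51.0%, 88.5% and 90.0% of them. Those simulated genes varied independently of each other, so the shares need not hold for these arrays.

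Camera called 10 lists under placebo, without a called member in any. The largest median was that of 22 skeletal muscle genes, -2.57 (adjusted p = 9.4e-10), whose score was 1.44, 3.35 and -1.26 in the wildtype placebo arrays and -2.69, 1.92 and -2.84 in the knockout placebo arrays. Medians were -0.43 for luminal genes (adjusted p = 1.7e-08), whose score was 0.03, -0.17 and 0.28 in wildtype and -1.12, -1.17 and 0.04 in knockout placebo, -0.14 for estrogen targets (adjusted p = 2.8e-04), 0.53 for genes of S, G2 and M phase (adjusted p = 5.8e-06) and 0.33 for fibroblast genes (adjusted p = 2.2e-04). The adjusted p with an estimated correlation was 0.70 for muscle, 0.64 for luminal genes, 0.15 for estrogen targets and 0.76 for the cell cycle and fibroblast lists. The cell cycle score ordered the arrays of both groups as the lymphocyte score did. Without wildtype placebo array 3 the mean of the cell cycle list was 0.022 instead of 0.53, without array 1 that of the fibroblast list was 0.066 instead of 0.33, and without array 2 that of the muscle list was -1.29 instead of -2.37. Camera with estimated correlations and fry each called 0 lists here. The 10 lists became 16 without wildtype placebo array 1, 6 without knockout placebo array 1 and 18 without knockout placebo array 2.

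Knockout against wildtype under estradiol compares the glands once both had the hormone. Several genes of epithelial cells were among the genes with the largest deficits. Krt19, a keratin of luminal cells, averaged 11.14 ± 0.72 in wildtype and 6.01 ± 1.66 in knockout (SD, n = 3) and was lower by 5.13 in log2 terms (difference -5.13, adjusted p = 0.027). The differences were -4.57 for Elf5 (adjusted p = 0.036), a transcription factor of alveolar cells, -3.95 for the tight junction gene Cldn7, -3.79 for Cdh1, the epithelial cadherin, -4.11 for the desmosomal gene Dsp, -3.64 for Perp (adjusted p = 0.0061) and -3.67 for the epithelial splicing regulator Esrp1. Ido1 differed by -5.20 (adjusted p = 0.011), Cxcl15 by -4.71 (adjusted p = 0.0061), Wfdc18 by -4.53, Slc5a8 by -4.09 (adjusted p = 0.0099), Muc15 by -3.73 and Tfap2c by -3.47. Slc5a8, Muc15 and Cel lay under the lower quartile in all 3 knockout estradiol arrays, so their deficits are at least the values given. Pgr was 2.47 lower (difference -2.47, adjusted p = 0.015), while Greb1 at -0.94 (adjusted p = 0.15) and Esr1 at 0.06 did not pass.

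Higher in knockout under estradiol were Fgl1 by 1.16, the kinase Pim1 by 1.06, Hopx by 0.94, Get4 by 0.65, Nt5dc1 by 0.59 and Zfand2b by 0.49. Another probe set of Get4 gave -0.034. Limma called 204 genes, 6 higher and 198 lower in knockout. In all 204 the 3 arrays of each group stood apart, as in 22.3% of all genes, where chance gives 10%. The count was 125 without wildtype placebo array 2, 315 without wildtype placebo array 3, 109 without wildtype estradiol array 2, 49 without wildtype estradiol array 3, 58 without knockout estradiol array 1, 32 without array 2 and 0 without array 3. None of the 32 named calls, Ccnd1 among them, survived the loss of knockout estradiol array 3. The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA quality, was 2.41 to 3.09 in wildtype estradiol and 3.22 to 3.56 in knockout estradiol, while that of beta-actin overlapped, averaging 2.77 and 2.62. With the Gapdh difference as a covariate, added after the data were seen, limma called 0 genes, and the median difference of the 204 was -1.08 (SE 0.261) against -1.23 (SE 0.203) without it.

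In the same arrays, which the Gapdh difference also separates, 8 of the 21 luminal genes were lower in knockout under estradiol (16 when adjusted over the list alone), with a median of -2.20 and adjusted p = 1.7e-20 by camera, 0.0079 by fry and adjusted p = 0.17 with an estimated correlation. Of the 16 basal genes 5 were lower (12 when adjusted over the list alone), among them Cnn1 (-2.15), the integrin Itgb4 (-1.61), Acta2 (-1.56) and the laminin Lama3 (-1.12), at adjusted p = 1.8e-12 by camera, 0.0056 by fry and adjusted p = 0.15 with an estimated correlation. Of the 30 estrogen targets 5 were lower (9 when adjusted over the list alone), namely Krt19, Elf5, Tfap2c, Pgr and Stc2 (-1.43), at adjusted p = 1.2e-05 by camera, 0.0016 by fry and adjusted p = 0.054 with an estimated correlation. Krt19 is also in the luminal list and Elf5 is a luminal gene, so this result is not separate from the luminal one. The target Greb1 did not pass. Of 32 Wnt and Notch genes Dkk3 was lower (-1.27), with 2 lower when adjusted over the list alone, at adjusted p = 4.6e-09 and adjusted p = 0.22 with an estimated correlation. Of 28 fibroblast genes Mmp14 was lower (-1.26), with 2 lower when adjusted over the list alone, and all 28 differences were below 0, at adjusted p = 3.6e-12 and adjusted p = 0.32 with an estimated correlation. Other genes lower in knockout were the receptor Erbb3 (-2.53), Sox10 (-2.19), the milk lipase Cel (-1.71), Igfbp2 (-1.17) and Pdgfa (-0.78). Another probe set gave 0.24 for Erbb3 and 0.016 for Lama3.

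Of the 35 lists, camera called 17 in the knockout under estradiol, fry 6, and camera with estimated correlations 0. B and T cell genes had medians of 1.06 and 0.94 in this comparison without passing, and their score was -1.85, 0.68 and -2.03 in wildtype estradiol and -2.04, 1.39 and 0.25 in knockout estradiol. White adipocyte genes had a median of 0.0013. The 2 genotype effects, under placebo and under estradiol, correlated at Pearson 0.174 and Spearman 0.0783 across genes, and 123 of the 204 genes called under estradiol had the same sign under placebo. Without wildtype placebo array 3 the Pearson correlation was -0.0114, without knockout placebo array 1 it was 0.0847 and without knockout estradiol array 2 it was 0.0782. Averaged over both treatments, limma called 0 genes for genotype, with a smallest adjusted p of 0.0687 and with 1845 at an unadjusted p under 0.05, where chance gives 910. The count was 66, 13 and 2 without wildtype estradiol arrays 1, 2 and 3, 19 without knockout placebo array 3 and 1 without knockout estradiol array 1.

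**Figure D3:**
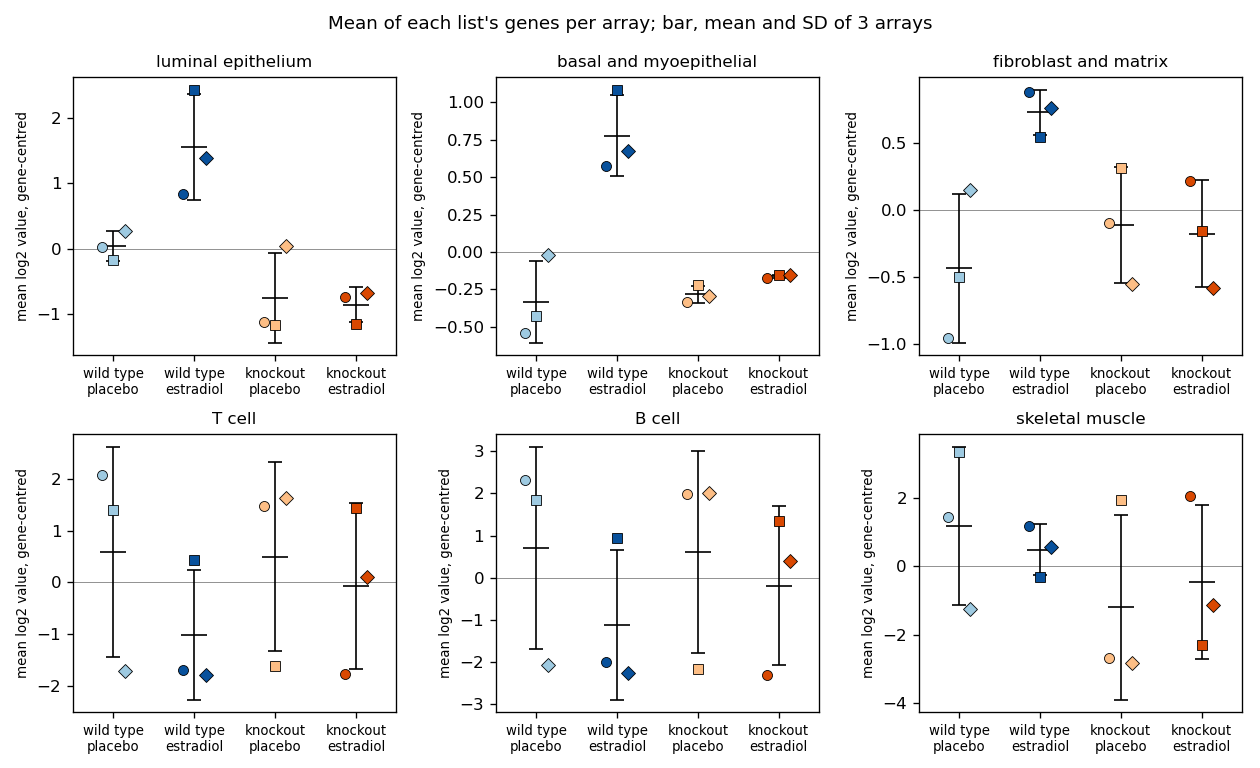
Mean log2 score of 6 gene lists (luminal, basal, fibroblast, T cell, B cell and skeletal muscle) in each array, centred over the 12 arrays; circle, square and diamond are replicates 1, 2 and 3. The luminal score averages 1.55 in wildtype estradiol and -0.85 in knockout estradiol, while T cell, B cell and muscle scores spread within groups.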

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

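The test of epithelial content and that of lymphocyte and muscle content were chosen only after the result was seen; the luminal and Gapdh covariates were also added after the data were seen, with their predictions stated before their results, and the splits of the arrays were set beforehand.

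The results here stand out because a test of the difference between the genotypes' estradiol responses passed its threshold, in limma for 2 genes and in camera with its preset correlation for 19 lists. With estimated correlations and by fry 0 of the 35 lists passed. The interaction was -1.96 for Anln and -2.14 for Padi4. Of 100 splits of the 12 arrays, 6 gave at least these 2 calls, the real one included and 3164 at most, so chance is not excluded for this count, and the high number in another split points to a structure of the samples that is described under the other observations.

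Among epithelial and stromal lists the median interaction was -1.79 for luminal genes, -0.97 for basal genes, -0.24 for milk protein genes, -1.28 for fibroblast genes and -0.48 for Schwann cell genes. It was -1.03 for macrophage genes and -0.82 for mast cell genes. Among lists of signalling and growth it was -0.19 for estrogen targets, -0.76 for genes of S, G2 and M phase, -0.33 for the EGF family, -0.32 for the FGF and IGF families, -0.49 for Wnt and Notch genes and -0.42 for immediate early genes. Higher in the knockout response were brown adipocyte genes (0.91), lipogenesis (0.22), cholesterol synthesis (0.64), oxidative phosphorylation (0.40), fatty acid oxidation (0.42) and skeletal muscle (1.66). Leaving out 1 array moved the mean of 12 of the 19 lists by over 1.5 times; among the lists that were higher, it fell without knockout estradiol array 1 from 1.43 to 0.17 for muscle, from 1.13 to 0.18 for brown adipocyte genes and from 0.42 to 0.075 for fatty acid oxidation, and milk protein genes turned their sign without wildtype placebo array 2 (from -0.19 to 0.037), wildtype estradiol array 2 (0.043) or knockout placebo array 3 (0.046).

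Probe sets that no single gene is linked to were left out of the comparisons, and of these 10092, limma called 15 under estradiol in wildtype, 14 of them higher. That is 0.149% of them, against 1.88% of the named genes.

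Luminal and basal genes were lower in knockout than in wildtype glands under estradiol. For the called genes, which include only part of these lists, a different share of lymph node or muscle in the tissue pieces is argued against. All 204 of the 204 called genes stayed called with lymphocyte and muscle scores as covariates, their median difference being -1.22 against -1.23 before. Genes that follow these scores vary within the groups and are less often called, which favours this outcome. It does not cover the genes of the lists that were not called. RNA quality that differs between the groups stays open: the Gapdh 3' minus 5' difference was 2.41 to 3.09 in wildtype and 3.22 to 3.56 in knockout estradiol, and with it as a covariate 0 of the 204 genes stayed called, their median difference going from -1.23 (SE 0.203) to -1.08 (SE 0.261) with all 204 signs kept, so the calls ended with a larger error and a slightly smaller difference. Fewer epithelial cells in the knockout pieces and lower expression per epithelial cell cannot be told apart: that both lists fell by fry (larger adjusted p 0.00788) restates the pattern, and the luminal covariate, which left 0 of the 204 calls, a median of -0.788 (SE 0.381) and 200 of the 204 signs, is made of genes that are part of the outcome. The lists share few genes with the others (3 of 21 luminal and 1 of 16 basal), and their most abundant members ranged over the arrays from 5.32 to 12.96 for Krt8 and from 10.45 to 12.67 for Acta2.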

How the results depend on the processing

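The lymphocyte, muscle, luminal and Gapdh covariates and the fits without the 2 lymphocyte-poor placebo arrays were chosen only after the result was seen; every other alternative was planned. The mean of all probe sets and quantile scaling left all counts of genes and lists within 1.5 times their value. Median scaling left all counts of genes within that range, and called lists were not counted under it. Across these alternatives, 297 to 352 genes were called for estradiol in wildtype and 179 to 219 for genotype under estradiol. The Ccnd1 difference stayed negative and past its test throughout, from -2.12 to -0.90. Of 242 results on named genes, 106 passed the test. Over 24 alternatives and omitted arrays, which leave out the single probe sets, other thresholds and fits of 6 arrays, these 106 kept their call 1846 times, lost it 674 times and turned their sign 1 time, and the results that did not pass stayed so 3076 times, passed 79 times and turned their sign 78 times. The 1 is Elf5, itself a luminal gene, for genotype under estradiol with the luminal covariate, with which 200 of all 204 called genes there kept their sign. Scaling moved the median of all genes by at most 0.018. The replicate numbers showed no consistent pairing of the arrays: correlations of arrays with equal numbers between groups ran from -0.741 to 0.660 in 12 pairs, of which 6 exceeded 0.1, and 5 of 12 fitted best with their own number. Lymphocyte genes differed many-fold within groups, so a smaller batch effect shared by equal numbers could go unseen here. Low signal against background limits dim genes; the filter below removes those with a low mean over all arrays, but not those low in 1 group, such as Greb1. Array weights gave a warning on convergence. Where a value moved, the cause was not tested, unless fewer genes, arrays or another threshold name it.

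Estradiol in wildtype called 4702 genes with array weights (3070 higher and 1632 lower), 158 with the replicate block, 715 at an adjusted p under 0.1 and 71 in a fit of its 6 arrays alone, which has 4 residual degrees of freedom. It called 702 with the lymphocyte covariate and 2154 without the 2 lymphocyte-poor placebo arrays, wildtype placebo 3 and knockout placebo 2, of which 594 fell. With the luminal covariate it called 12; the median size of the 342 differences went from 1.37 (SE 0.225) to 1.33 (SE 0.325) with all 342 signs kept, so the calls ended with a larger error. Estradiol in knockout called 73 with array weights, 10 with the block, 30 at 0.1 and 5 in 6 arrays, 54 with the lymphocyte covariate, 54 with lymphocyte and muscle covariates, 11 with the luminal covariate and 50 without the 2 arrays. Called in both genotypes were 60 with array weights, 9 with the block, 32 with the lymphocyte covariate, 33 with both covariates, 7 with the luminal covariate and 46 without the 2 arrays.

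The interaction called 5 probe sets when each was tested on its own, 0 without the dimmest 40% of genes, which include Padi4, 1 with a trend and robust priors, 84 with array weights, 0 with the block, 4 at 0.1, 72 with the lymphocyte covariate, 24 with both, 0 with the luminal and 0 with the Gapdh covariate. The median size of its 2 calls was 2.05 (SE 0.223), 1.83 (SE 0.282) with the luminal and 1.99 (SE 0.225) with the Gapdh covariate. Without the 2 arrays it called 3, of which 0 were the same genes. Genotype under placebo called 4 with array weights and 1 without the 2 arrays. Genotype under estradiol called 119 without the dimmest genes, 428 with array weights, 45 with the block, 473 at 0.1, 47 in 6 arrays, 986 with the lymphocyte covariate, 788 with both, 0 with the luminal covariate, 0 with the Gapdh covariate and 472 without the 2 arrays.

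The average estradiol effect called 4835 with array weights, 134 with the block, 585 at 0.1, 145 with a log2 difference of at least 1, 566 with the lymphocyte covariate, 456 with both, 95 with the luminal covariate, 506 with the Gapdh covariate and 3913 without the 2 arrays. The average genotype effect called 1 probe set on its own, 198 with array weights, 43 at 0.1, 134 with the lymphocyte covariate, 45 with both and 5 without the 2 arrays. Lists called fell to 0 in each of the 5 main comparisons with estimated correlations, and fry called 9 for estradiol in wildtype, 0 for estradiol in knockout, 0 for the interaction, 0 for genotype under placebo and 6 for genotype under estradiol. For estradiol in knockout camera called 7 lists with the lymphocyte covariate, 2 with both, 8 with the Gapdh covariate and 10 without the 2 arrays. For genotype under placebo it called 5 with the luminal covariate. The correlation of the 2 estradiol responses was 0.554 with array weights, 0.302 with the lymphocyte covariate, 0.313 with both, 0.397 with the luminal covariate and 0.616 without the 2 arrays, and that of the genotype effects was 0.546 with the luminal covariate, 0.564 with the Gapdh covariate and 0.0893 without the 2 arrays.

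Leaving out 1 array at a time, genes called ranged from 100 to 1146 for estradiol in wildtype, 10 to 25 for estradiol in knockout, 0 to 18 for the interaction, 0 to 2 for genotype under placebo, 0 to 315 for genotype under estradiol, 127 to 1400 for the average estradiol effect, 0 to 66 for the average genotype effect and 9 to 23 for both genotypes. Lists called ranged from 14 to 17, 3 to 10, 16 to 19, 6 to 18 and 16 to 20 in the 5 main comparisons in that order. Correlations ranged from 0.307 to 0.507 for the estradiol responses and from -0.0114 to 0.260 for the genotype effects, and Ccnd1 from -2.12 to -1.65.

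Apart from Elf5, sign changes concern results that passed no test. With array weights the value was 0.15 for Ccnd2 for estradiol in wildtype, 0.089 for Ccnd2 for estradiol in knockout, 0.081 for Esr2 for estradiol in knockout, -0.13 for Ccnd3 in the interaction and 0.051 for Esr1 in the interaction. With the 2 arrays left out the value was 0.079 for Ccnd2 for estradiol in wildtype, 0.089 for Esr2 for estradiol in wildtype, 0.070 for Esr2 for estradiol in knockout, -0.14 for Ccnd3 in the interaction, -0.019 for Esr2 in the interaction and 0.048 for Esr2 for genotype under placebo. With the mean of probe sets the value was -0.24 for Ccnd3 for estradiol in wildtype, -0.16 for Ccnd3 for estradiol in knockout, 0.11 for Ccnd2 in the interaction and 0.0069 for Esr1 in the interaction. With quantile scaling the value was -0.014 for Ccnd3 for estradiol in wildtype, -0.013 for Ccnd3 for estradiol in knockout, 0.011 for Esr2 for estradiol in knockout and -0.026 for Esr2 for genotype under estradiol. With the lymphocyte covariate the value was -0.053 for Ccnd3 for estradiol in wildtype and 0.11 for Esr1 in the interaction. With both covariates the value was -0.15 for Ccnd3 for estradiol in wildtype, 0.026 for Ccnd2 in the interaction, 0.21 for Esr1 in the interaction, -0.093 for Ccnd3 for genotype under placebo and -0.021 for Esr1 for genotype under placebo. With the Gapdh covariate the value was -0.010 for Ccnd3 for estradiol in wildtype, 0.038 for Esr2 for estradiol in knockout, 0.12 for Esr1 in the interaction and 0.10 for Esr2 for genotype under placebo. With the luminal covariate the value was 0.076 for Esr2 for estradiol in wildtype, -0.11 for Ccnd3 in the interaction, -0.088 for Esr2 in the interaction, -0.11 for Ccnd3 for genotype under estradiol, 0.11 for Elf5 for genotype under estradiol, -0.30 for Esr1 for genotype under estradiol, -0.17 for Esr2 for genotype under estradiol, 0.18 for Ier3 for genotype under estradiol and 0.80 for Kit for genotype under estradiol. With median scaling the value was 0.015 for Esr2 for estradiol in knockout. For estradiol in wildtype, leaving out 1 array gave -0.21 to 0.082 for Ccnd2, -0.073 to 0.16 for Ccnd3 and -0.19 to 0.089 for Esr2. For estradiol in knockout, leaving out 1 array gave -0.40 to 0.075 for Ccnd2, -0.052 to 0.085 for Ccnd3 and -0.089 to 0.070 for Esr2. In the interaction, leaving out 1 array gave -0.34 to 0.14 for Ccnd2, -0.13 to 0.099 for Ccnd3, -0.40 to 0.33 for Esr1 and -0.093 to 0.19 for Esr2. For genotype under placebo, leaving out 1 array gave -0.014 to 0.21 for Ccnd3, -0.27 to 0.46 for Esr1 and -0.16 to 0.12 for Esr2. For genotype under estradiol, leaving out 1 array gave -0.15 to 0.33 for Ccnd2, -0.0011 to 0.16 for Ccnd3, -0.24 to 0.27 for Esr1 and -0.0095 to 0.092 for Esr2.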

Other observations

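Of the tests below, those on lymphocyte genes, the lymphocyte covariate and those on strain haplotypes, mislabelling and the Trim genes, Hal and Cxcl16 were chosen only after the result was seen.

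Gene lists of other tissues in and around the gland give a background to the comparisons. White adipocyte genes, which mark the fat that makes up most of the gland, had medians of 0.025 in the wildtype response, 0.071 in the knockout response, 0.011 for genotype under placebo and 0.0013 under estradiol, and camera called the list in none of these. Skeletal muscle genes reached from 5.81 to 14.01 on the log2 scale between arrays for Acta1 and from 4.41 to 13.87 for Myh4, both contractile proteins of skeletal muscle. The 34 measured genes near Ccnd1 on its chromosome had medians of -0.023 and -0.052 for genotype under placebo and estradiol, with 0 called by limma over all genes and 1 lower under estradiol when adjusted over the list alone. Keratinocyte, erythroid, ribosomal protein and clock lists were not called by camera in any of the 5 main comparisons.

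The first principal component held 48.1% of the variance and the second 15.3%. Control probe sets at the 3' end of Gapdh and beta-actin were brighter than those at the 5' end in all 12 arrays, by 2.10 to 3.56 log2 units for Gapdh, with 2.10 to 3.26 in wildtype placebo, 2.41 to 3.09 in wildtype estradiol, 3.20 to 3.31 in knockout placebo and 3.22 to 3.56 in knockout estradiol.

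Lymphocyte genes differed many-fold between arrays of 1 group, with scores of 2.21, 1.63 and -1.90 in wildtype placebo, -1.85, 0.68 and -2.03 in wildtype estradiol, 1.73, -1.89 and 1.83 in knockout placebo and -2.04, 1.39 and 0.25 in knockout estradiol. Abundant members ranged from 9.08 to 13.22 for Ighm and from 4.55 to 11.35 for Il7r, and 1 of 17 T cell and 1 of 16 B cell genes is also in another list. The white adipocyte score ranged over only 20.5% of the range of the lymphocyte score (0.868 against 4.24). This cannot test a loss of signal shared by all cell types, since quantile normalisation evens out such a loss before the scores are taken. An effect of RNA quality on certain genes stays open, which adipocyte genes cannot test. The array poorest in lymphocyte genes had the lowest Gapdh 3' minus 5' difference of its group in wildtype placebo (2.10), knockout placebo (3.20) and knockout estradiol (3.22). In wildtype estradiol it had the highest (3.09). Lymph node tissue in some pieces is a candidate explanation, as T and B cell scores ordered the 3 arrays alike in 4 of 4 groups. That estradiol lowered lymphocyte content stays open, with a difference of -1.20 and an exact two-sided permutation p of 0.27 over 400 arrangements within genotypes.

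The splits of the arrays show the same structure. For the average estradiol effect, 2 of 100 splits gave at least the 287 genes of the real one, the real one included. This share is under 0.05, but another split gave 3164, so the count also follows other differences between the samples than treatment. That split exchanged wildtype placebo array 3 with wildtype estradiol array 2 and knockout placebo array 2 with knockout estradiol array 2, and thereby parts the 6 arrays with the higher lymphocyte scores from the 6 with the lower; with the lymphocyte score as a covariate the real split gave 566 genes. For the average genotype effect, with 0 genes in the real split, the count of splits that reach it (100 of 100, with 261 genes at most) was bound to be complete and decides nothing. In the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05: 1 of 10 reached the 342 genes of wildtype, 1 of 10 the 18 of knockout and 1 of 10 the 204 of genotype under estradiol, the highest other split giving 0 in each, while under placebo, where the real count was also 0, all 10 had to reach it, with 1 at most.

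In 5 genes, Trim34a, Trim30d, Hal, Cxcl16 and Pou2af1, the arrays were parted by a gap of over 2 log2 units that does not follow the groups. Mislabelled arrays are argued against, because 12 of 12 arrays had Ccnd1 on the side of their genotype and Mmd2 on that of their treatment. Mmd2 was picked for its rise between these same labels, so its split alone decides nothing. Greb1, a gene fixed beforehand, was at most 4.64 in the placebo arrays and at least 8.32 in the estradiol arrays. Lymph node tissue is argued against for Trim34a and Trim30d, whose highest values in wildtype placebo arrays 1 and 2 (4.78 and 3.64) lay at least 3.16 below the lowest of 5 other arrays rich in lymphocyte genes (8.61 and 6.80); lymph node or muscle is argued against for Hal, which was 4.37 higher in 2 of the 5 arrays poor in lymphocyte genes than in the other 3, whose muscle scores lay between those of the 2; and either alone is argued against for Cxcl16, which was 3.20 lower in wildtype placebo array 3 and knockout placebo array 2 than in the 2 of these 5 arrays with a muscle score between theirs, both of wildtype estradiol, so that a joint effect with the treatment stays open. For Pou2af1, a B cell gene low in the same 5 arrays, lymph node tissue stays open, and the regression on both scores, after which 20% of the 5 genes kept such a gap, decides nothing. Strain haplotypes that segregate between the mice cannot be told apart from shared probe signal: 1 pair with the same split lay within 2 Mb (0.0027 in permuted positions, permutation p = 0.0028), and both its genes belong to the Trim family, with 0 pairs of other families. Both genes of the pair lie on the chromosome of Ccnd1. They were low only in wildtype placebo arrays 1 and 2, and high in the other wildtype arrays and in every knockout array. Whether their split is tied to the targeted chromosome was not tested.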
